A study of Mus musculus with 11 samples.

How the data were processed

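Total RNA of pulverized back skin was reduced to mRNA and sequenced for 11 mice treated with imiquimod, 5 wild type and 6 Trex2 knockout, per the labels' protocols. The submitters describe the samples of each group as biological replicates, and genotype is the only factor that the labels vary. They give no batch, litter or sequencing date. The replicates are numbered 2 to 6 in wild type and 7 to 12 in knockout.

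The deposited table gives a normalized signal, a count divided by 1 size factor per library, for 38406 gene symbols. Per the submitters' processing notes, TopHat2 2.0.8, featureCounts 1.4.6, DESeq2 1.8.1 and the build GRCm38 were used. The order of the tools, the annotation version and the strand setting are not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart. Each column of the table carries a replicate number and was matched to the sample with that number in its title. Every value was a whole multiple of the value of 1 read in its library (100% within 0.01 of a whole read), so whole reads were recovered by dividing by that step. No row named anything other than a gene. Reads were not deduplicated by molecular identifiers as far as the labels say, and intervals from reads cover counting error only. No 2 libraries agreed within sampling noise (lowest chi-square per degree of freedom 4.74), so each counted as 1 replicate.

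The main test was limma 3.58.1 in R 4.3.3, with moderated variances and a mean-variance trend, on log2(normalized count + 1) of genes with a mean of at least 10 over all libraries. The Benjamini-Hochberg adjusted p threshold was 0.05. Fold changes are knockout relative to wild type on the log2(value + 1) scale, which understates the change of low genes. Trex2 and 39 gene lists of pathways and cell types of skin were fixed before the data were examined, as were the tests and most alternatives. Lists with at least 5 tested members (36 of 39) were tested with camera of limma at its preset correlation of 0.01, two-sided, adjusted over lists, and again with a correlation estimated from these libraries. The fry test of limma was also run, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. A list score is the mean of log2(value + 1) over tested members, each centred on its mean over the 11 libraries, and was compared by exact permutation (462 splits, two-sided). Of the list symbols 10 were found under an older name in a RefSeq gene table. The lists share some members. For example, 5 of 18 neutrophil genes, 3 of 33 type I interferon genes, 5 of 15 T cell and dendritic cell chemokines and 1 of 50 differentiation genes also stand in another list, and many markers of immune cells are also expressed by other cells of skin.

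Genes were named by a rule fixed beforehand. It took Trex2, genes past the threshold with a mean of at least 50 and no placeholder name, up to 4 called members of each list or else the 2 of smallest p, and the genes beside Trex2. Some genes that the rule takes are not reported here. Other members named in the text, and Rnu3a, Irx3, Prss23, Mest, Ndn and the genes described with them, were chosen after their values were seen. Positions come from GENCODE M21 on GRCm38, where 94.2% of tested genes had a position by symbol.

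The scripts were tested on simulated counts for the 13215 genes of this comparison with 200 genes changed. They recovered 70% of genes changed by a log2 fold change of 1 and 98% of those changed by 2, with 0 in the wrong direction and 5 unchanged genes called. A shifted list was recovered and 0 of 35 unshifted lists were called. Genes were drawn independently throughout, unlike in tissue. Neither the recovered shares nor the list calls therefore give the power of the tests in these libraries. Depth per library was 1208896 to 15557862 counted reads, and the 3 reads taken as the limit of detection correspond to 1.04 to 13.5 normalized counts.

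Alternatives were pseudocounts of 0.5 and 5, no filter or a minimum of 50, TMM, upper quartile and quantile scaling, robust variances, array weights, covariates for muscle, hair follicle and adipocyte content, and leaving out each library. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads. Added after the data were seen were a fit without knockout replicates 9 and 12, reads thinned to 1208896 per library, a depth covariate, only the libraries of 3000000 to 8000000 reads, voom on recovered reads and the permutation of list scores.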

Results

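RNA was sequenced from the back skin of female C57BL/6 mice, 8 to 10 weeks old, after treatment with imiquimod, an agonist of the innate receptor TLR7 whose cream is used to produce psoriasis-like inflammation in mouse skin. Each mouse received 125 mg of 5% cream on each of 4 days, and skin was collected 24 hours after the final dose. The 11 libraries came from 5 wild-type mice and 6 mice lacking Trex2, which encodes a 3′-to-5′ DNA exonuclease made mainly in keratinocytes. No skin without imiquimod was analysed here, so each value compares the genotypes within treated skin. The libraries held 1208896 to 5853454 counted reads in wild type and 3125366 to 15557862 in knockout. Depth differed between the groups (exact permutation test, two-sided, p = 0.0281). The table lists 38406 genes. Reads were found for 22225 of them, and the 13215 with a mean normalized count of at least 10 were tested.

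The first comparison asked whether the targeted gene was lost and whether the genes beside it were altered. Trex2 fell from 1480 ± 446 normalized counts in wild-type skin (SD, n = 5) to 1.85 ± 0.91 in knockout skin (SD, n = 6), which is 0.125% of the wild-type mean. The wild-type replicates 2, 3, 4, 5 and 6 had 2196, 1245, 1633, 1198 and 1125 normalized counts of Trex2. The knockout replicates 7 to 12 had 1.74, 1.39, 0.794, 1.58, 2.14 and 3.47, so every library carried the level that its label gives. In recovered reads, Trex2 had 4992 in wild type and 22 in knockout. The log2 fold change was −9.03 (SE 0.25, limma adjusted p = 5.5e-11), and the exact permutation test gave p = 0.00216, the smallest that 462 splits allow. The annotation (GRCm38, GENCODE M21) places Trex2, ENSMUSG00000031372.7, on the minus strand of chromosome X from 73433705 to 73435344.

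RP23-95K12.12, a transcript named after a genomic clone, rose in the same skin. It had 0.628 ± 1.4 normalized counts in wild type (SD, n = 5) and 150 ± 67.5 in knockout (SD, n = 6), with all 6 knockout libraries above every wild-type library. The log2 fold change was 6.73 (SE 0.41, limma adjusted p = 1.16e-06). Only 2 of its reads were in wild type, both in replicate 6, against 1788 in knockout, a ratio of read rates of 298 with a 95% interval of 82.3 to 2459 that covers counting error only. RP23-95K12.12 is not in GENCODE M21, but its row in the table stands between Zfp275 and Zfp92, 3 rows before Trex2, and 99.4% of 31169 adjacent rows on a chromosome were in order of gene start. The annotated neighbours of Trex2 that were tested did not pass the limma threshold, which only Trex2 and RP23-95K12.12 passed among all genes. Zfp92, in the row next to Trex2, Atp2b3 and Pnck were too low to be tested. Haus7, a subunit of the augmin complex of the mitotic spindle, had a log2 fold change of 0.21 (SE 0.19, adjusted p = 0.499). Zfp275 stood at −0.12 (SE 0.16, adjusted p = 0.665). Bgn, the proteoglycan biglycan of the dermis, stood at −0.63 (SE 0.19, adjusted p = 0.109), Dusp9, a MAP kinase phosphatase, at 0.74 (SE 0.22, adjusted p = 0.109) and Slc6a8, the creatine transporter, at 0.42 (SE 0.16, adjusted p = 0.149).

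**Figure D1:**
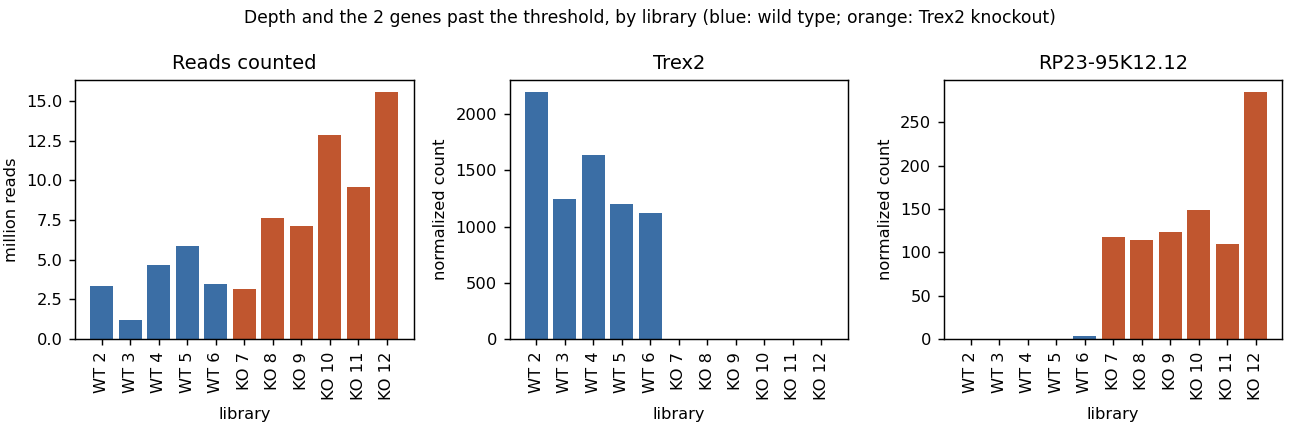
Bars give, for each of the 5 wild-type (WT, blue) and 6 knockout (KO, orange) libraries, the counted reads (left) and the normalized counts of Trex2 (middle) and RP23-95K12.12 (right), on linear axes from 0. Trex2 lies between 1125 and 2196 in wild type and at most at 3.47 in knockout, while RP23-95K12.12 shows the opposite arrangement.

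The second comparison asked which other genes differ between treated knockout and treated wild-type skin. Trex2 and RP23-95K12.12 were the 2 genes past an adjusted p of 0.05. Gzma, the cytotoxic granule protease granzyme A, came next among protein-coding genes with 168 ± 62.3 normalized counts in wild type and 46.4 ± 11.9 in knockout (SD, n = 5 and 6). Its log2 fold change was −1.77 (SE 0.29, limma adjusted p = 0.0985), and all 6 knockout libraries lay below every wild-type library. Rnu3a, a U3 small nucleolar RNA chosen after its values were seen, had 40.2 ± 15.7 and 7.21 ± 3.07 normalized counts (SD, n = 5 and 6; log2 fold change −2.32, SE 0.37, limma adjusted p = 0.0985). edgeR on the recovered reads called these 2 as well (adjusted p = 0.0444 for Gzma and 0.0385 for Rnu3a). At an adjusted p of at most 0.1 there were 4 genes, and many more followed between 0.1 and 0.2. An unadjusted p under 0.05 was found for 3225 genes (24.4% of those tested), 1705 higher and 1520 lower in knockout, where 661 are expected by chance, and 3128 had an adjusted p of at most 0.2. Among 100 splits of the libraries, the real one included, the highest other had 3081. That count of 3225 was 538 with log10 depth as a covariate, which is partly confounded with genotype, and 1017 with hair follicle content as a covariate. It was 1124 in libraries of 3000000 to 8000000 reads, 1658 without knockout replicates 9 and 12 and 2081 without knockout replicate 12 alone. The hair follicle covariate was the mean of 6 genes, whose list score was −0.40 in wild type and 0.33 in knockout. It was highest in knockout replicates 9 and 12, as was the terminal differentiation score. That covariate can therefore remove part of the group difference itself. DESeq2 on the recovered reads called 617 genes, 329 higher and 288 lower. Leaving out wild-type replicate 4 gave limma 740 calls, 462 higher and 278 lower, of which 438 were also called by DESeq2, all in the same direction. The terminal differentiation score of that library was 0.71, against −1.48 to −0.40 in the other wild-type libraries and a knockout mean of 0.57. Leaving it out therefore widens the group difference for such genes. The counts without it, here and below, are not an independent check.

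Interferon-stimulated genes fell as a list in knockout skin. Of 33 tested genes induced by type I interferon 32 had a negative log2 fold change, with a median of −0.43. Of the 4 below the minimum level for testing, 1 had a lower mean in knockout, 2 a higher one and 1 no reads. The mean score of the list was 0.21 ± 0.09 in wild type and −0.18 ± 0.18 in knockout (log2, SD, n = 5 and 6), a ratio of 0.764, and all 6 knockout libraries lay below every wild-type library. Bst2, which tethers budding virus to the cell surface, had 245 ± 49.8 normalized counts in wild type and 143 ± 46.8 in knockout (log2 fold change −0.81, SE 0.22). Rtp4, another interferon-induced gene, had a log2 fold change of −0.72 (SE 0.21). None of the 33 passed alone in limma, whether over all genes tested or adjusted over the list alone, while over all genes DESeq2 called 2 lower and so did limma without wild-type replicate 4. The list gave adjusted p = 7.37e-07 in limma camera, adjusted p = 0.296 with an estimated correlation and adjusted p = 0.0197 in fry. It was 1 of 2 lists that passed an exact permutation test of the score per library (p = 0.00216, adjusted p = 0.039). Without knockout replicates 9 and 12 the median was −0.27.

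Genes of interferon gamma response and antigen presentation also fell as a list, with 24 of 29 members negative and a median log2 fold change of −0.37. B2m, the light chain of MHC class I, had 10110 ± 163 normalized counts in wild type and 6548 ± 1288 in knockout (SD, n = 5 and 6; log2 fold change −0.65, SE 0.16). Tapbp, the chaperone tapasin that loads peptides on class I molecules, stood at −0.57 (SE 0.13), and for both genes all 6 knockout libraries lay below every wild-type library. Over all genes tested none of the 29 passed in limma, against 6 lower in DESeq2 and 4 lower without wild-type replicate 4, and adjusted over the list alone 8 were lower. The camera test gave adjusted p = 1.51e-05, and adjusted p = 0.296 with an estimated correlation, and fry gave adjusted p = 0.0188. Without knockout replicates 9 and 12 the median was −0.23. Chemokines that draw T cells and dendritic cells fell as a list as well, with 12 of 15 negative, a median of −0.48 and adjusted over the list alone 3 lower. Ccl5, a chemokine made by activated T cells and natural killer cells, had 100.5 ± 37.3 normalized counts in wild type and 37.2 ± 13.1 in knockout (log2 fold change −1.37, SE 0.35), and Ccl11, the eosinophil chemokine eotaxin, stood at −0.64 (SE 0.19). Over all genes DESeq2 called 2 of them lower, and limma called 0, or 1 without wild-type replicate 4. This list gave adjusted p = 0.00353 in camera, adjusted p = 0.296 with an estimated correlation and adjusted p = 0.0188 in fry. It passed the exact permutation test of the score (p = 0.00216, adjusted p = 0.039).

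Genes of natural killer and other cytotoxic cells were lower in all 10 tested members, with a median log2 fold change of −1.12. The 14 below the minimum level also had a lower mean in knockout. Besides Gzma, Klra4, a receptor of the Ly49 family on natural killer cells, stood at −1.37 (SE 0.32) with 19.7 ± 7.41 and 6.88 ± 2.17 normalized counts in wild type and knockout (SD, n = 5 and 6). Adjusted over the list alone 8 of the 10 were lower. Over all genes tested limma called none, or 4 lower without wild-type replicate 4, and DESeq2 called 3 lower. Camera gave adjusted p = 3.03e-06, and adjusted p = 0.351 with an estimated correlation, and fry gave adjusted p = 0.0254. The score was 0.57 ± 0.48 in wild type and −0.47 ± 0.44 in knockout (exact permutation p = 0.00866, adjusted p = 0.0779).

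Neutrophil markers were negative in all 18 tested members, with a median log2 fold change of −1.02. Stfa2l1, a stefin A family member abundant in neutrophils, had 2138 ± 789 normalized counts in wild type and 769 ± 477 in knockout (SD, n = 5 and 6; log2 fold change −1.61, SE 0.40). Mmp9, the gelatinase stored in neutrophil granules, had 2309 ± 495 and 1134 ± 578 (log2 fold change −1.19, SE 0.34). Of the 18, 15 were lower when adjusted over the list alone. Over all genes tested limma called 0, or 2 lower without wild-type replicate 4, and DESeq2 called 3 lower. Camera gave adjusted p = 1.63e-08, and adjusted p = 0.441 with an estimated correlation. Chemokines and receptors that draw neutrophils and monocytes were negative in 20 of 21 members (median −0.76, adjusted p = 7.76e-06, and adjusted p = 0.441 with an estimated correlation). Saa3, an acute-phase protein, had a log2 fold change of −1.33 (SE 0.35), Cxcl5, a neutrophil attractant, −1.34 (SE 0.39), and these were the 2 lower when adjusted over the list alone. Monocyte and macrophage markers were negative in 22 of 26 (median −0.59, adjusted p = 1.51e-05, and adjusted p = 0.441 with an estimated correlation), and adjusted over the list alone 6 were lower. Among them were Ly6c2, a marker of inflammatory monocytes, at −1.52 (SE 0.42), and Plac8 at −1.08 (SE 0.30). In each of these 2 further lists limma called 0 over all genes, or 2 lower without wild-type replicate 4, and DESeq2 called 2 lower. Without knockout replicates 9 and 12 the medians of the 3 lists shrank to −0.59, −0.28 and −0.30.

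**Figure D2:**
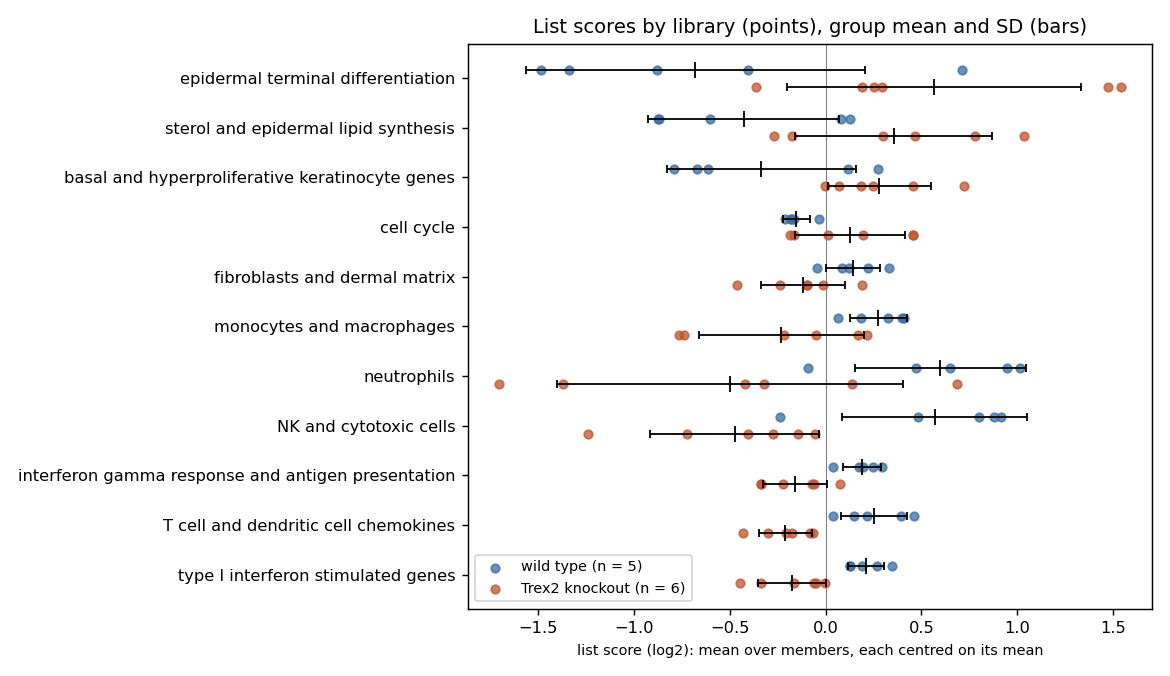
Points are libraries (blue, 5 wild type; orange, 6 knockout), the horizontal axis is the list score on a log2 scale, and black bars give the group mean and SD. The groups do not overlap for type I interferon genes or for T cell and dendritic cell chemokines, while 1 wild-type library lies among the knockout libraries for epidermal terminal differentiation.

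Keratinocyte genes moved the other way. Genes of epidermal terminal differentiation rose as a list in knockout skin, with 48 of 50 tested members positive and a median log2 fold change of 1.12. Ivl, which encodes the cornified envelope protein involucrin, had 240 ± 102 normalized counts in wild type and 722 ± 313 in knockout (SD, n = 5 and 6; log2 fold change 1.57, SE 0.31). Abca12, the lipid transporter of lamellar granules, had 357 ± 245 and 1131 ± 666 (log2 fold change 1.70, SE 0.39). No member passed over all genes tested in limma, against 18 higher without wild-type replicate 4 and 7 higher in DESeq2, and adjusted over the list alone 27 were higher. Camera gave adjusted p = 3.3e-12, and adjusted p = 0.441 with an estimated correlation. The score was −0.68 ± 0.89 in wild type and 0.57 ± 0.77 in knockout, a ratio of 2.37, with 2 of 6 knockout libraries above every wild-type library. Genes of sterol and epidermal lipid synthesis rose likewise, with 23 of 24 positive, a median of 0.83 and adjusted over the list alone 18 higher (adjusted p = 8.53e-09, and adjusted p = 0.441 with an estimated correlation). Over all genes limma called 0 of the lipid genes, or 6 higher without wild-type replicate 4, and DESeq2 called 5 higher. Without knockout replicates 9 and 12 the medians of these lists were 0.71 and 0.51.

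Basal and hyperproliferative keratinocyte genes were positive in 26 of 30 members, with a median log2 fold change of 0.79 (camera adjusted p = 2.14e-05, and adjusted p = 0.441 with an estimated correlation). Cdh3, the P-cadherin of basal cells, had 247 ± 115 normalized counts in wild type and 533 ± 177 in knockout (SD, n = 5 and 6; log2 fold change 1.16, SE 0.29). Ereg, an EGF receptor ligand, stood at 0.63 (SE 0.16) with all 6 knockout libraries above every wild-type library. Adjusted over the list alone 10 were higher and 2 lower, the latter being the interleukin 1 receptor antagonist Il1rn (log2 fold change −0.82) and the pantetheinase Vnn3 (−0.94). Cell cycle genes rose by a smaller amount, with 38 of 40 positive and a median of 0.25 (adjusted p = 1.51e-05, and adjusted p = 0.491 with an estimated correlation). Adjusted over the list alone 2 were higher, Cdc20, an activator of the anaphase-promoting complex, at 0.68 (SE 0.17), and Mcm2, a subunit of the replicative helicase, at 0.53 (SE 0.14). Over all genes limma called 0 in both lists, or 7 basal genes and 1 cell cycle gene higher without wild-type replicate 4, and DESeq2 called 6 and 2 higher. Without knockout replicates 9 and 12 the medians were 0.47 and 0.10.

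The late cornified envelope genes, a cluster of epidermal structural genes, rose as a list with 20 of 21 positive and a median of 0.71 (adjusted p = 0.0058, and adjusted p = 0.614 with an estimated correlation). Lce1c had a log2 fold change of 2.08 (SE 1.01) and Lce1k 1.33 (SE 0.69), and no member passed when adjusted over the list alone. With hair follicle content as a covariate the envelope list reversed to a median of −0.31 (adjusted p = 0.00945). That covariate was highest in knockout replicates 9 and 12, as was the terminal differentiation score. It can therefore remove part of the group difference itself. Of 38 hair follicle and hair shaft genes only 6 were tested, and all 6 were positive (median 0.74, adjusted p = 0.0304, and adjusted p = 0.447 with an estimated correlation). Most hair keratins and keratin-associated proteins of that list lay below the minimum level, and of its 31 genes there 14 had a lower mean in knockout, 10 a higher one and 7 no reads. Foxn1, a transcription factor of follicle keratinocytes, had a log2 fold change of 0.98 (SE 0.30) and was the 1 higher when adjusted over the list alone, and Tchh, the inner root sheath protein trichohyalin, stood at 0.62 (SE 0.28). The call of the envelope list was lost without wild-type replicate 5 (median 0.40, adjusted p = 0.154) or knockout replicate 9 (0.45, adjusted p = 0.0936). That of the hair list was lost without wild-type replicate 5 (0.66, adjusted p = 0.103), wild-type replicate 6 (0.50, adjusted p = 0.0923) or knockout replicate 9 (0.59, adjusted p = 0.0731), and with thinned reads (0.74, adjusted p = 0.0711). Without knockout replicates 9 and 12 together the medians were 0.17 (adjusted p = 0.571) and 0.34 (adjusted p = 0.202).

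**Figure D3:**
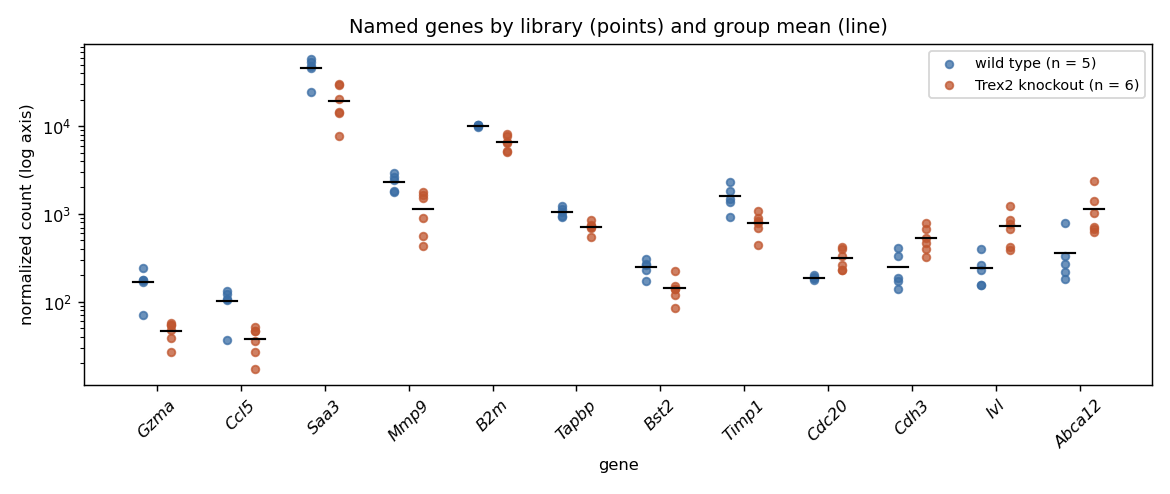
Points are the normalized counts of 12 named genes in each library (blue, 5 wild type; orange, 6 knockout) on a log axis, and lines are group means. B2m and Tapbp show no overlap between the groups, whereas Abca12 and Cdh3 do.

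Genes of the dermis and its vessels fell as lists too. Fibroblast and dermal matrix genes were negative in 28 of 34 members (median −0.26, adjusted p = 0.000227, and adjusted p = 0.441 with an estimated correlation), and adjusted over the list alone 5 were lower. Timp1, an inhibitor of metalloproteinases, had 1587 ± 529 normalized counts in wild type and 788 ± 219 in knockout (SD, n = 5 and 6), and Thy1, a surface marker of fibroblasts, had a log2 fold change of −0.70 (SE 0.19). Endothelial and lymphatic genes were negative in 21 of 23 (median −0.41, adjusted p = 0.000248, and adjusted p = 0.512 with an estimated correlation), with Egfl7 at −0.88 (SE 0.30) and Robo4 at −0.65 (SE 0.22), and none passed when adjusted over the list alone. Over all genes limma called 0 in both lists, or 4 lower in each without wild-type replicate 4, and DESeq2 called 5 fibroblast genes lower and 0 endothelial genes. Their medians were −0.14 and −0.11 without knockout replicates 9 and 12, and the endothelial call was lost there (adjusted p = 0.163). Without knockout replicate 9 alone the endothelial median was −0.25 (adjusted p = 0.0133).

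The other 4 lists past the threshold each lost their call without 1 library, though not always with a smaller fold. Erythroid and platelet genes were negative in 5 of 6 (median −0.79, adjusted p = 0.0221, and adjusted p = 0.446 with an estimated correlation), among them the globin Hba-a1 (−1.11, SE 0.39) and the platelet chemokine Pf4 (−0.82, SE 0.30), the 2 lower when adjusted over the list alone. Without wild-type replicate 3 the median was −0.55 (adjusted p = 0.0886). Apoptosis and pyroptosis genes were negative in 16 of 23 (median −0.36, mean −0.14, adjusted p = 0.0215, and adjusted p = 0.447 with an estimated correlation). Casp6, an executioner caspase, had a log2 fold change of −0.62 (SE 0.15) and was the 1 lower when adjusted over the list alone, and Casp4, an inflammatory caspase, stood at −0.77 (SE 0.27). The median was −0.33 without wild-type replicate 6 (adjusted p = 0.0563) and −0.25 without knockout replicate 9 (adjusted p = 0.0549). Genes of mast cells, basophils and eosinophils were negative in 11 of 12 (median −0.28, adjusted p = 0.0163, and adjusted p = 0.441 with an estimated correlation). Kit, the stem cell factor receptor, stood at −0.37 (SE 0.16) and Mrgprb2, a mast cell receptor, at −0.75 (SE 0.33), and none passed when adjusted over the list alone. Without wild-type replicate 4 or 6 the adjusted p was 0.11 and 0.0614, with medians of −0.17 and −0.24. Schwann cell and nerve genes were negative in 9 of 14 (median −0.20, adjusted p = 0.0413, and adjusted p = 0.351 with an estimated correlation). Adjusted over the list alone 5 were lower and 1 higher, the latter being Egr2, a transcription factor, at 0.70 (SE 0.20). The Schwann cell call was lost without wild-type replicate 4 (median −0.21, adjusted p = 0.102) or 5 (−0.22, adjusted p = 0.107) or knockout replicate 8 (−0.24, adjusted p = 0.0533), 9 (−0.23, adjusted p = 0.0502) or 11 (−0.14, adjusted p = 0.0567). Its median was −0.35 without wild-type replicate 2 or knockout replicate 7 and 0.02 with thinned reads (adjusted p = 0.426). None of these 4 lists passed without knockout replicates 9 and 12 together. The medians there were −0.47 for erythroid (adjusted p = 0.0896), −0.14 for apoptosis (adjusted p = 0.122), −0.15 for mast cell (adjusted p = 0.15) and −0.26 for Schwann cell genes (adjusted p = 0.0572), so the last grew while the other 3 shrank.

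The camera test did not call the lists closest to the function of Trex2 as a nuclease. Nuclease and DNA sensing genes had 10 positive and 15 negative members with a median log2 fold change of −0.03 and a mean of 0.01 (adjusted p = 0.563), and adjusted over the list alone 2 were higher and 4 lower. Dnase1l2, the deoxyribonuclease that degrades DNA in cornifying keratinocytes, had 265 ± 112 normalized counts in wild type and 570 ± 238 in knockout (SD, n = 5 and 6; log2 fold change 1.08, SE 0.33). Ifi204, an interferon-inducible DNA sensor, stood at −0.61 (SE 0.18). The 35 genes of p53 response and DNA damage had 18 positive and 17 negative members (median 0.04, adjusted p = 0.934), and none passed when adjusted over the list alone. Atr, a kinase of the replication checkpoint, had a log2 fold change of 0.74 (SE 0.21) and Bax, a pro-apoptotic protein, −0.62 (SE 0.21).

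The interleukin 23 and 17 axis, central to the imiquimod model, was split between 10 positive and 9 negative members (median 0.00, adjusted p = 0.613). Over all genes limma called 0 of them, or 3 higher and 1 lower without wild-type replicate 4, and DESeq2 called 2 higher and 1 lower. Adjusted over the list alone 4 were higher, the cytokines Il1f6 (interleukin 36 alpha; 1.83, SE 0.62) and Il19 (0.70, SE 0.23) and the receptor genes Il17re (1.02, SE 0.27) and Il17rc (0.92, SE 0.29), and 2 were lower, the iron-binding protein Lcn2 (−1.49) and the cytokine Il1a (−0.72). The cytokines Il17a, Il22, Il17f, Ifng and Il23a were near the limit of detection. In normalized counts Il17a had 0.445 ± 0.995 in wild type and 0.265 ± 0.648 in knockout (SD, n = 5 and 6), Il22 0.495 ± 0.717 and 0.378 ± 0.698, and Il17f 0 and 0.380 ± 0.653. Ifng had 1.8 ± 2.77 and 0.436 ± 0.675, and Il23a 9.24 ± 8.67 and 7.20 ± 3.57. These 5 lay below the minimum level and were not tested, and each difference is smaller than the larger SD of its gene. Antimicrobial peptides and alarmins had 13 positive and 13 negative members (median −0.06, mean −0.20, adjusted p = 0.156), with S100a8, a calcium-binding alarmin of neutrophils and inflamed keratinocytes, at −1.12 (SE 0.34), and adjusted over the list alone Stfa2l1 was the 1 lower. Over all genes limma called 0 of this list, or 3 lower without wild-type replicate 4, and DESeq2 called 3 lower.

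Among other epidermal lists, the small proline rich genes (10 of 14 positive, median 0.30, adjusted p = 0.193), hair follicle stem and outer root sheath genes (10 of 14 positive, 0.54, adjusted p = 0.313) and sebaceous gland genes (10 of 16 positive, 0.67, adjusted p = 0.457) did not pass. Lrig1, a stem cell regulator, was the 1 follicle stem gene higher when adjusted over the list alone (0.65, SE 0.15), and of the sebaceous genes Cyp4f39 (1.02, SE 0.27) was 1 of 2 higher and Mgst1 (−0.60, SE 0.16) the 1 lower. Immediate early and stress genes had 15 of 26 positive (median 0.09, adjusted p = 0.338), with Fosb, an AP-1 subunit, at 1.61 (SE 0.45) among 4 higher when adjusted over the list alone. Among lists of other cell types, T cells (4 of 6 negative, −0.72, adjusted p = 0.16), Langerhans and dendritic cells (8 of 14 negative, −0.32, adjusted p = 0.384), B cells and plasma cells (6 of 8 negative, −0.26, adjusted p = 0.769) and melanocytes (5 of 7 positive, 0.07, adjusted p = 0.63) did not pass. Nor did skeletal muscle (21 of 29 negative, −0.23, adjusted p = 0.0667), smooth muscle and pericytes (9 of 15 negative, −0.24, adjusted p = 0.107) or adipocytes (13 of 21 negative, −0.26, adjusted p = 0.13). Counted with p adjusted over the list alone, 2 T cell genes, 2 smooth muscle genes and 1 dendritic cell gene were lower. The dendritic cell gene was Bst2, which also stands in the type I interferon list, so its fall cannot be assigned to dendritic cells. In the B cell and plasma cell list 1 gene, Sdc1, was higher, and 0 were called in the other lists of that group. Sdc1 had means of 2018 in wild type and 3448 in knockout, against 4.91 and 2.89 for Mzb1 of the same list. Its rise therefore cannot be assigned to plasma cells. Only 6 of 25 T cell genes reached the minimum level. Of the 19 below it 16 had a lower mean in knockout and 3 a higher one, among them Cd3d (6.25 ± 3.04 and 1.67 ± 0.742 normalized counts) and Cd2 (13.99 ± 5.65 and 5.41 ± 2.43). The 6 tested had a mean log2 fold change of −0.21, and the fry test gave adjusted p = 0.0254. Their score did not pass by exact permutation (p = 0.223, adjusted p = 0.349), with 0 of 6 knockout libraries below every wild-type library. That overlap came from wild-type replicate 3, the shallowest library, whose T cell score was −0.50. The other wild-type libraries had scores of 0.14 to 0.48, and the knockout libraries −0.34 to 0.08. Circadian genes (median 0.08, mean −0.01, adjusted p = 0.934) and mitochondrially encoded genes (median −0.01, mean 0.01, adjusted p = 0.934) had 0 calls when adjusted over the list alone.

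Of the 17 lists that did not pass, 7 did under another setting of camera or in fry. With an estimated correlation on all libraries none of these 7 passed in camera (adjusted p from 0.441 to 0.657). T cell genes passed as lower with no minimum level (median −0.57, adjusted p = 0.000573) and in libraries of 3000000 to 8000000 reads (−0.82, adjusted p = 0.0362). Antimicrobial peptides and alarmins passed as lower without knockout replicate 9 (−0.18, adjusted p = 0.0457), without knockout replicates 9 and 12 (−0.22, adjusted p = 0.00635), with array weights (−0.22, adjusted p = 0.0149) and with skeletal muscle (−0.12, adjusted p = 0.039) or hair follicle content (−0.19, adjusted p = 0.0283) as a covariate. Immediate early and stress genes passed as higher without knockout replicates 9 and 12 (0.24, adjusted p = 0.00134), with the depth covariate (0.37, adjusted p = 0.000168), in the depth window (0.23, adjusted p = 0.017) and with skeletal muscle (0.26, adjusted p = 0.0226) or hair follicle content (0.14, adjusted p = 0.00575) as a covariate. Skeletal muscle genes passed as lower in 5 of 11 fits without 1 library, which were those without wild-type replicate 3 (−0.25, adjusted p = 0.0411) or 4 (−0.32, adjusted p = 0.0174) or knockout replicate 7 (−0.31, adjusted p = 0.0232), 10 (−0.22, adjusted p = 0.0466) or 11 (−0.31, adjusted p = 0.0116). They also passed with no minimum level (adjusted p = 0.0265) and in the depth window (adjusted p = 0.0191), but their median was 0.01 without knockout replicates 9 and 12 (adjusted p = 0.571). Small proline rich genes passed as higher without knockout replicate 11 (0.43, adjusted p = 0.0488), with the depth covariate (0.29, adjusted p = 0.0263), in the depth window (0.50, adjusted p = 0.000244) and with adipocyte content as a covariate (0.44, adjusted p = 0.0132). Smooth muscle and pericyte genes passed as lower without knockout replicate 10 (−0.27, adjusted p = 0.0466), with no minimum level (adjusted p = 0.045) and in the depth window (adjusted p = 0.0341). Adipocyte genes did so without knockout replicate 7 (−0.29, adjusted p = 0.04997), with array weights (adjusted p = 0.0485) and with hair follicle content as a covariate (−0.19, adjusted p = 0.0226).

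Of the 36 lists tested, 19 passed in camera with its preset correlation, 6 higher and 13 lower. With an estimated correlation none passed (lowest adjusted p = 0.296), and 10 of 100 splits of the 11 libraries, the real one included, gave 19 or more lists. Fry, which does not compare a list with other genes, called 5 lists, all lower. They were type I interferon genes, interferon gamma and antigen presentation genes, T cell and dendritic cell chemokines, natural killer and cytotoxic genes, and T cell genes. The lists too short to test were gamma delta T cells (3 members, 1 lower when adjusted over the list alone), sex-linked transcripts and C57BL/6 substrain differences. The lower gene, Fcer1g, had means of 3263 in wild type and 1942 in knockout, against 3.29 and 1.32 for Trdv4. Its fall therefore cannot be assigned to gamma delta T cells. Xist, the X inactivation transcript, had 536 ± 143 normalized counts in wild type and 760 ± 209 in knockout (SD, n = 5 and 6). Of the substrain genes, Nnt had a log2 fold change of 0.08 (SE 0.14) and Wdfy1 −0.31 (SE 0.12), the latter lower when adjusted over the list alone.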

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

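The tests of tissue composition and of knockout replicates 9 and 12 were chosen after the result was seen, as were the fits with thinned reads, a depth covariate or a depth window. The other tests here were set beforehand.

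Within 236 groups of values, 17 had 1 library far from the rest, where about 11.8 are expected by chance. Wild-type replicate 4 accounts for 8 of them. On the log2(value + 1) scale it was the low library for Saa3 (14.57, others 15.48 to 15.81), Cxcl5 (10.21, others 11.38 to 11.58), Ccl5 (5.24, others 6.73 to 7.04), Ly6c2 (6.88, others 7.97 to 8.37), Bax (8.11, others 8.91 to 9.11) and Egfl7 (7.59, others 8.69 to 9.10). It was the high one for Sprr2b (6.64, others 2.46 to 3.38). Its smooth muscle and pericyte score was low as well (−0.0350, others 0.11 to 0.16). Its epidermal terminal differentiation score of 0.71 lay above the other wild-type libraries (−1.48 to −0.40) and above 4 knockout libraries, while its Trex2 level was that of wild type (1633 normalized counts).

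Wild-type replicate 6 had the only wild-type reads of RP23-95K12.12 (2.05, others 0), a low B2m (13.26, others 13.31 to 13.32), a high cell cycle score (−0.0324, others −0.21 to −0.16) and a low melanocyte score (−0.52, others −0.04 to 0.03). Wild-type replicate 2 had a high Cfd, the adipocyte protease adipsin (13.06, others 11.77 to 12.13), and a high adipocyte score (0.65, others −0.15 to 0.07). Knockout replicate 12 had a high RP23-95K12.12 (8.16, others 6.79 to 7.22) and a low Tnnt1, a slow muscle troponin (2.55, others 3.89 to 4.45). Knockout replicate 9 had a high B cell and plasma cell score (0.40, others −0.25 to −0.07). Below the minimum level for testing, RP23-95K12.9, the clone-named row next to RP23-95K12.12, had 49 reads over the knockout libraries and 0 in wild type. Those reads scale to 16.3 at the depth of the wild-type group, above the 3 that a count of 0 allows. The clone-named AC110382.1 had 39 reads over the knockout libraries, which scale to 12.98, and 0 in wild type.

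Several keratinocyte lists were higher and several immune lists lower in knockout skin by camera with its preset correlation, but no list passed with an estimated correlation (lowest adjusted p = 0.296), and T cell, dendritic cell, B cell and small proline rich genes passed in neither. Across all 11 libraries, the group difference included, the scores of terminal differentiation and neutrophils had r = −0.858 (permutation p = 0.00084, adjusted over 6 relations p = 0.00423; rho = −0.736, p = 0.0128, adjusted p = 0.0753), r = −0.896 without the 2 libraries farthest from the median, and r = −0.858 within the 6 knockout libraries (adjusted p = 0.0862; rho = −0.657, p = 0.174, adjusted p = 0.261), with no value for the 5 wild-type libraries. The terminal differentiation median was 1.16 after thinning every library to 1208896 reads. Thinning tests unequal counting only, and not RNA or library differences that go with depth. Log10 reads and the terminal differentiation score had r = 0.580 over all libraries (permutation p = 0.0598, adjusted p = 0.0897). It was r = 0.198 without wild-type replicate 3 and knockout replicate 12, and r = 0.233 within the knockout libraries. Against knockout replicates 9 and 12 as the sole cause of that list, its median was 0.71 without them, although 7 of the 19 lists lost their call there. A larger share of epidermis in the knockout pieces and lower inflammation cannot be told apart, as none of 6 differences passed after adjustment: neutrophil minus fibroblast score differed by −0.84 (exact permutation p = 0.0693, adjusted over the 6 p = 0.139), neutrophil minus skeletal muscle score by −0.91 (p = 0.0281, adjusted p = 0.0844) and natural killer minus fibroblast score by −0.78 (p = 0.0195, adjusted p = 0.0844), but monocyte minus fibroblast score by −0.24 (p = 0.169, adjusted p = 0.253) and type I interferon minus fibroblast score by −0.13 (p = 0.485, adjusted p = 0.582), and natural killer minus neutrophil score by 0.05 (p = 0.911). The Trex2 genotype stays open as an untested biological cause, beside RNA or library quality that goes with the unequal depth, and chance is not excluded for the number of lists, as 10 of 100 splits, the real one included, gave 19 or more and the highest other gave 22. The split with 22 had 1 wild-type library in its group of 5, so it kept part of the genotype contrast.

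The 2 genes past the threshold and the 3225 with an unadjusted p under 0.05 were each matched by 1 of 100 splits, the real one itself. The highest other split had 0 genes past the threshold, but the 2 genes are the deleted one and RP23-95K12.12, which the table lists 3 rows before it, so that comparison says nothing about other genes. For the unadjusted count the highest other split had 3081, with 1 wild-type library in its group of 5, so it kept part of the genotype contrast. The real split was thus the highest of the 100 drawn from 462. Its margin was smaller than the range from 2081 without knockout replicate 12 to 3888 without wild-type replicate 4. The count was 538 with the depth covariate. The splits therefore do not settle whether chance is excluded for that count.

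RP23-95K12.12 was higher where Trex2 was absent. The 40 tested genes within 1 Mb of Trex2 had a median absolute t of 0.97, below the 1.30 of 351 other genes of the X chromosome (one-sided permutation p = 0.901). That argues against a change of the genes in this window as a whole. A median over the window cannot show a change limited to the genes closest to Trex2. RP23-95K12.12 and RP23-95K12.9 have no annotated position and were not part of the test. Why it is higher stays open, since the table holds counts per gene and not the positions of reads along the locus, which would show where its transcript starts.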

How the results depend on the processing

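The fits without knockout replicates 9 and 12, with thinned reads, a depth covariate, a depth window or voom, and the permutation of scores were chosen after the data were seen. Trex2 was called in all 31 settings (log2 fold change −9.52 to −7.72) and so was RP23-95K12.12 (4.72 to 7.79, largest adjusted p = 0.00479). The number of genes past the threshold was 2 except with array weights (6, adding Gzma, Rnu3a, Irx3 and Prss23), edgeR (4) and DESeq2 (617). Leaving out 1 library gave 2 to 740 genes: 740 without wild-type replicate 4, 3 without wild-type replicate 2 (adding Irx3) and 2 without any other. The cause was not tested. The unadjusted count of 3225 fell to 538 with log10 depth as a covariate, which is partly confounded with genotype, to 1017 with hair follicle content, to 1124 in libraries of 3000000 to 8000000 reads and to 1658 without knockout replicates 9 and 12. The number of lists was 19, or 21 with no minimum level, 16 with a minimum of 50, 21 with array weights, 16 to 21 without 1 library, 0 with an estimated correlation, 5 with fry and 2 by permutation of scores. It was 14 without knockout replicates 9 and 12 (12 of them among the 19), 17 with thinned reads, 20 with the depth covariate and 23 in the depth window. With hair follicle content as a covariate, 15 lists passed and the late cornified envelope list reversed to a median of −0.31 (adjusted p = 0.00945). The cause was not tested, and the covariate holds follicle keratinocyte genes. It was highest in knockout replicates 9 and 12, as was the terminal differentiation score, so it can remove part of the group difference itself. Of the other named genes, 0 reversed while past the threshold. Robust variances do not enter camera, and edgeR and DESeq2 gave genes only. No paired analysis was possible because the groups share no replicate number. Shallow wild-type libraries limit low genes: 3 reads correspond to 13.5 normalized counts in wild-type replicate 3 and to 1.04 in knockout replicate 12.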

Other observations

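The genes described here were chosen after their values were seen, while the bounds of the 2 tests were set before their results. Some of the genes of smallest p stand side by side in the genome. On chromosome 16, Stfa2l1, Gm5483 and 2010005H15Rik, which belong to the stefin A cluster of cysteine protease inhibitors, had log2 fold changes of −1.61 (SE 0.40), −1.81 (SE 0.44) and −1.83 (SE 0.38). Gm5483 had 734 ± 279 normalized counts in wild type and 236 ± 142 in knockout (SD, n = 5 and 6). On chromosome 17, Psmb8 and Psmb9, catalytic subunits of the immunoproteasome, stood at −0.72 (SE 0.18) and −0.68 (SE 0.17), and Psmb8 had 440 ± 73.8 and 271 ± 60.1 normalized counts. On chromosome 8, Cdh1, the E-cadherin gene next to Cdh3, stood at 0.92 (SE 0.24), with 794 ± 291 normalized counts in wild type and 1472 ± 437 in knockout. Each of these had a limma adjusted p of 0.108.

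Such pairs would be more frequent than by chance if segments of another strain's genome had been carried along with the targeted allele. Among the 200 genes of smallest p, 8 pairs lay within 100 kb, all 8 with both genes in the same direction, against a median of 5 and a highest count of 13 in 1000 draws of genes matched on level (permutation p = 0.117). The bound set beforehand counted any p of 0.05 or more against the idea. That was wrong, because a count above the median of the draws excludes nothing. The 8 pairs lay on chromosomes 4, 7, 8, 9, 16 and 17, and none on X, where Trex2 lies. Segments linked to Trex2 therefore do not account for these pairs. Unlinked passenger segments may still contribute, and chance cannot be told apart from them. The draws were matched on level only, so the count also cannot tell such segments from neighbours that move together for other reasons. The pairs are not independent, as Gm5483 stands in both stefin A pairs. Rab4b and Gm21983, which start at 27168424 and 27168430 of chromosome 7, had near-equal log2 fold changes of −0.71 and −0.73.

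Mest and Ndn, which are imprinted and expressed from the paternal allele in growing mesenchymal tissue, were among the genes of smallest p. Mest had 197 ± 54.7 normalized counts in wild type and 76.1 ± 36.8 in knockout (SD, n = 5 and 6; log2 fold change −1.44, SE 0.30), and Ndn had 191 ± 32.4 and 115 ± 15.4 (−0.72, SE 0.15). Phlda2, imprinted with expression from the maternal allele, went the other way with 43.9 ± 9.38 and 78.2 ± 11.2 (0.83, SE 0.18), and the limma adjusted p was 0.108 for each of the 3. A hypothesis is that imprinted genes are lower as a group, and it was tested on 19 others, of which 14 were negative and 5 positive. Their median log2 fold change was −0.16, short of the −0.2 that had been set as the bound, while their score was 0.12 ± 0.07 in wild type and −0.10 ± 0.18 in knockout (exact permutation p = 0.039). Adjusted over these 19 genes alone, Cdkn1c (−0.68, SE 0.20) and Rian (−0.67, SE 0.20) were lower, so the test leaves the hypothesis open, and many of these genes are expressed by fibroblasts, whose list was lower too. Phlda2 was not among the 19, so their score leaves out a gene known to go the other way.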
